A study of Mus musculus with 6 samples.

How the data were processed

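The data were 6 arrays of total RNA, 1 per tumour, labelled with biotin and hybridised to an Affymetrix GeneChip 3′ expression array. The deposited values were probe-set intensities on a linear scale, 1 for each of 45101 probe sets and each array. The values showed that they had been summarised to probe sets and brought to a common scale before deposit, since the array medians lay between 77.7 and 82.6, but the summarisation method, the normalization and the software are not given in the sources used here. Of all values, 4201 (1.55%) stood at exactly 1, which has the look of a floor, and 12 probe sets had a value below 1. No further normalization was applied in the main setting, and the log2 of each intensity was taken with no pseudocount. Arrays carry no read depth, so the number of arrays limits the precision.

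Probe sets were named through the platform annotation given with the data. A single gene symbol was listed for 34958 probe sets and several symbols for 932, and 9211 were unnamed in that table. Probe sets with several symbols named no gene. Symbols were updated by Entrez identifier with a table of RefSeq genes of the assembly GRCm38.p6, in which the identifiers of 34754 probe sets matched. Since the deposited values name no assembly, no coordinates are given. Each of 18194 genes was represented by its probe set with the highest mean. Probe sets of 1 gene can differ, and levels of different genes are not comparable as amounts of RNA, because probe sets differ in affinity. Columns of per-sample values that could not be tied to a sample numbered 0.

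Background on each array was the 95th percentile of 47 olfactory receptor probe sets, of which 3 named several receptors. Each gene's log2 intensity minus that threshold was fitted with an intercept in limma 3.58.1 (R 4.3.3) with eBayes and an intensity trend, and genes with a mean above 0 were called by a one-sided moderated test with Benjamini-Hochberg adjustment at 0.05. Variability between tumours was tested over genes above background by comparing the residual variance on 5 degrees of freedom with limma's robust trend prior by an F test, with the same adjustment. The study has 1 group, so these tests ask about level and spread, not about a difference between conditions.

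A total of 30 gene lists were fixed before the data were examined. They cover Wnt feedback targets, Wnt components, ligands and receptors, synovial sarcoma genes, BAF and Polycomb subunits, hindlimb position genes, epithelial, matrix and fibroblast, cartilage and bone, tendon and joint, mature muscle, myogenic, adipocyte, macrophage, T and NK cell, B and plasma cell, neutrophil, erythroid, endothelial, mural, Schwann cell and keratinocyte genes, proliferation, interferon, hypoxia and glycolysis, immediate early, sex-linked and housekeeping genes, and markers of other organs. A list score is the mean, over members above background, of the log2 value minus the member's mean over the tumours, and 26 lists had the 4 members it needs. Coherence is the mean pairwise Pearson correlation between members, and variability is the median SD of members. Both were placed among 10000 random lists of the same size matched on level in 20 bins, as descriptions with no p-value. A set of 8 pairs of scores was tested by exact permutation of the 6 tumours (720 orders, two-sided), with members shared by both lists left out. Median shifts of a list in 1 tumour are differences from the median of the other 5 tumours and were not tested, because the tumour was chosen for standing apart.

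The text names genes by a rule fixed beforehand: the first 3 measured members of each list, the 15 called variable genes with the largest SD, and any Wnt feedback target. The second part gave no gene, since 0 were called. Members outside the rule that are named where 5 or fewer passed or failed, and Wnt ligands that passed, were chosen after their values were seen. A further 7 lists used only in the closing section were also written after the values were seen, and their scores and coherence are over all measured members, whether or not above background.

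The tests were tested on simulated data. In an 18194-gene simulation of the background test, 33 of 50 genes set 0.5 above background on the log2 scale were called, 48 of 50 at 1 and 50 of 50 at 2, and 8 of 4927 genes set below background were called. A 13217-gene simulation of the variability test used the spread of variances fitted over all 18194 genes, dim ones included. In it 0 of 50 genes were called at SDs 5, 10 or 20 times larger and 3 of 50 at 40 times. With nearly equal variances all 50 were called at each size. The exact correlation test gave p under 0.05 in 49 of 1000 simulations without a relation.

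Alternatives were the 99th percentile of background, a value above the threshold in each tumour, quantile normalization, arrays centred on their medians, the mean of a gene's probe sets, no filter on dim genes, a non-robust prior, all measured list members, median or scaled scores, Spearman's rho, scaled genes for the principal components or muscle and sex-linked genes left out of them, the first component of the olfactory receptor probe sets regressed out, and each tumour left out in turn. Alternatives added after seeing the data were a background set without Olfr78 and Olfr558, list members near the top of the scale left out, and each tumour left out of the correlations.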

Results

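Gene expression was measured in 6 tumours of a mouse model of synovial sarcoma, a soft-tissue cancer driven by a fusion of SS18, a subunit of the BAF chromatin remodelling complex, with an SSX gene. The mice were C57BL/6 animals that carried 1 copy of a Cre-dependent SS18-SSX2 transgene at the Rosa26 locus. They also carried 1 copy of Ctnnb1, the gene of beta-catenin, with an exon flanked for excision by Cre, whose loss removes the residues that mark the protein for degradation. A viral vector expressing Cre was injected at 4 weeks of age into the anterior compartment of both legs, at 10000000 units, and the mice were 4 months old at sampling. The sample labels name an adenoviral Cre vector and the text for the series names an adeno-associated one. Total RNA of each tumour was hybridised to 1 Affymetrix 3′ expression array with 45101 probe sets. The series title asks about expression after beta-catenin stabilisation in this tumour. All 6 tumours shared genotype and treatment, and samples without the stabilised allele were not analysed here, so no contrast between groups was made. The values below describe which transcripts the tumours held, at what level, and how far the tumours differed. The labels call the tumours biological replicates but do not tie them to mice, so the p-values measure only the spread between these 6 samples.

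The arrays had median signals between 77.7 in tumour 5 and 82.6 in tumour 4. Over genes above background, the closest pair was tumours 2 and 4, with a Pearson correlation of 0.988 across genes and a median absolute difference of 0.12 on the log2 scale. The most distant pair by correlation was tumours 2 and 5, at 0.831 with a median absolute difference of 0.39 and 2497 genes more than 2-fold apart. Tumour 3 correlated with tumours 1, 2, 4 and 6 at 0.907 to 0.916. The 18S ribosomal RNA signal was 6641 in tumour 5 and 4930 in tumour 3, and ran from 1172 to 4227 in the others. Genes are not independent replicates, so these correlations are descriptions of the arrays. Of 18194 named genes, 12581 (69.1%) lay above background by limma's one-sided test at an adjusted p of 0.05, where background was each array's own 95th percentile of 47 olfactory receptor probe sets. A total of 12225 genes exceeded the threshold on all 6 arrays. Markers of organs other than leg tissue set the limit of this rule. Of 17 such genes measured, 5 passed (4 when adjusted over the list alone). They were Prm1, Pomc, Cela1, Gfap and Slc17a7, and 4 of them had means of 5.35 to 5.97, close to the thresholds of 4.55 to 5.17. At the 99th percentile of the olfactory receptor probe sets 1 of the 17 passed. Cela1 stood at 8.06 ± 1.45 (SD, n = 6). For every other list below, the count adjusted over the list alone equalled the count adjusted over all genes. Each list count is to be read against the 69.1% of all genes that passed. All signals below are log2 values.

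Negative-feedback and other direct targets of canonical Wnt signalling were present in every tumour. Of 16 measured members of the list fixed before the data were examined, 14 lay above background, and the same number passed when adjusted over the list alone. Axin2, a scaffold of the beta-catenin destruction complex that is itself a Wnt target, had a mean of 11.84 ± 0.65 (SD, n = 6; limma adjusted p = 8.78e-10). Lef1, a DNA-binding partner of beta-catenin, had a mean of 10.58 ± 0.46. The Dishevelled antagonists Nkd1 and Nkd2 stood at 11.05 ± 1.35 and 12.25 ± 0.54, and Notum, a secreted enzyme that inactivates Wnt ligands, stood at 11.24 ± 0.99. Rnf43 and Znrf3, ubiquitin ligases that remove Wnt receptors, stood at 8.44 ± 0.94 and 8.50 ± 0.79. The stem-cell receptors Lgr5 and Lgr6 had means of 7.93 ± 1.81 and 9.98 ± 0.57, Bmp4 had 9.75 ± 1.53 and the secreted antagonist Dkk1 had 6.69 ± 0.70. Another 3 members lay near the top of the arrays' scale, where the highest gene mean was 13.98. Apcdd1 had 13.74 ± 0.05, Wif1 had 13.32 ± 0.16 and Tnfrsf19 had 13.01 ± 0.14, and differences between tumours are compressed there. Dkk4 stayed below background in every tumour. Sp5 did not pass as a group mean, at 5.97 ± 2.56, but exceeded the threshold in tumours 3 and 5 with values of 8.14 and 10.05. Tcf7 was not measured, because no probe set was named for it alone in the annotation used.

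**Figure D1:**
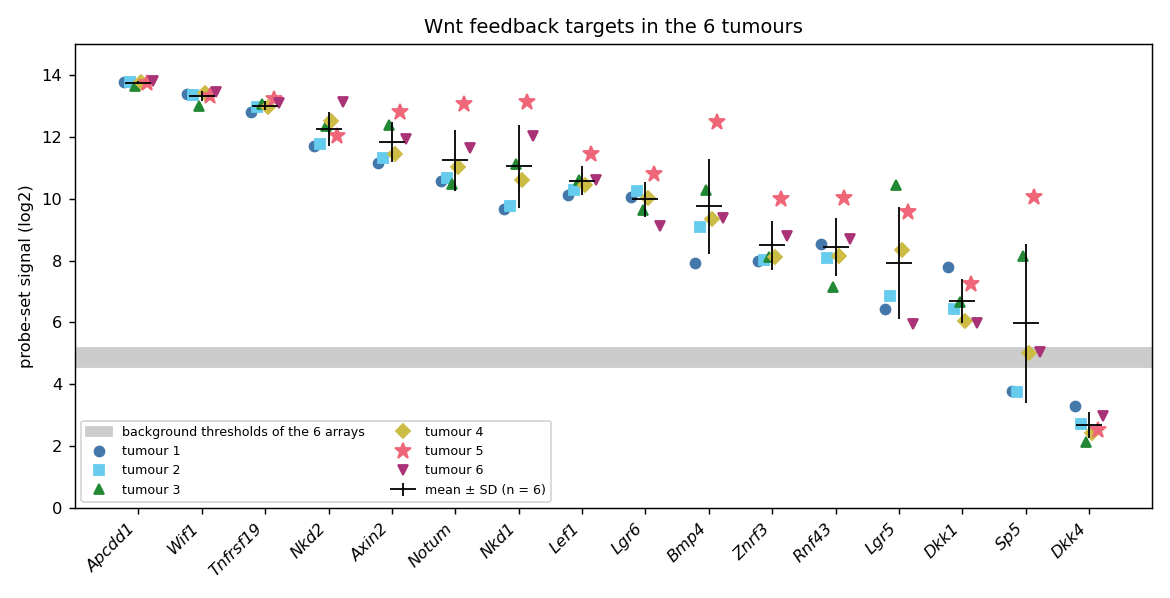
Signals (log2) of the 16 measured Wnt feedback targets, each symbol being 1 tumour, with the mean and SD over the 6 tumours as a black bar and the range of the 6 background thresholds as a grey band. Apcdd1, Wif1 and Tnfrsf19 lie close together near the top of the scale, whereas Lgr5 spans 22.3-fold and Nkd1 spans 11-fold between tumours, and Sp5 lies far above the band in tumours 3 and 5.

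The Wnt targets differed in level between tumours and did so partly together. Tumour 5 was the highest of the 6 for Axin2 (12.79), Lef1 (11.45), Nkd1 (13.14), Notum (13.06), Rnf43 (10.01), Znrf3 (10.00) and Bmp4 (12.47), and its members lay above the median of the other 5 tumours by a median of 1.18 (SD over 14 members 1.13), or 2.26-fold, with 11 of 14 higher. That median includes Apcdd1, Wif1 and Tnfrsf19, near the top of the scale, with shifts of -0.04, -0.07 and 0.27, and may understate the rise. Lgr5 was highest in tumour 3, at 10.43, and Nkd2 was highest in tumour 6, at 13.13. The list score, the mean deviation of the members from their 6-tumour means, was 1.04 in tumour 5 and ran from -0.46 to 0.04 in the others. The median between-tumour SD of the members was 0.68, at the 100th percentile of 10000 random lists matched on level. The mean pairwise correlation among members was 0.305 and lay at percentile 99.8 of the random lists. Without tumour 5 it was 0.0751, and the median SD was 0.49. High places among the random lists were not particular to Wnt targets. The median SD stood at percentile 99.99 for Wnt receptors, 99.92 for proliferation and 100 for macrophage genes. Wnt components and housekeeping genes lay at 41.3 and 0.95. Coherence was 0.922 for proliferation and 0.938 for macrophage genes, both at percentile 100, and 0.0307 for Wnt components, at percentile 76.3.

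Other parts of the Wnt pathway passed to differing extents, where 69.1% of all genes passed. Of 21 pathway components, 20 lay above background, with Dvl3 below it. Ctnnb1 itself had a mean of 13.16 ± 0.22, from 12.94 in tumour 1 to 13.58 in tumour 5. Whether its probe sets cover the excised exon was not examined, so recombination was not checked here. Apc, the core of the destruction complex, stood at 10.00 ± 0.09 and Axin1 at 9.16 ± 0.23. Among 19 Wnt ligands, 9 passed, a smaller share than over all genes. Wnt4, Wnt5a, Wnt5b, Wnt6, Wnt7b, Wnt9a, Wnt10a, Wnt11 and Wnt16 were those 9, with Wnt5a at 11.51 ± 0.50. The first ligands of the list, Wnt1, Wnt2 and Wnt2b, did not pass, with means of 3.02, 2.32 and 3.88. Of 20 receptors and secreted modulators, 18 passed, Frzb and Sfrp5 being the exceptions. The Frizzled receptors Fzd1, Fzd2 and Fzd3 stood at 12.85 ± 0.21, 9.45 ± 0.29 and 7.85 ± 0.68. The component score lay between -0.03 and 0.03, with members that moved both ways. In tumour 5 Porcn was 6.58-fold lower and Bcl9 2.55-fold higher than the median of the others (both chosen after their values were seen). The ligand score ran from -0.17 in tumour 3 to 0.36 in tumour 5.

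Genes tied to synovial sarcoma mostly passed, where 69.1% of all genes passed. Of 18 measured, 16 lay above background. Tle1, a Groucho-family corepressor used as a diagnostic marker of this tumour, had a mean of 11.20 ± 0.40, and Bcl2, an inhibitor of apoptosis, had 10.05 ± 0.23. Sox2 and Zic2 did not pass. Sox2 had a mean of 4.40 ± 2.48, with values of 8.82 in tumour 3 and 5.89 in tumour 5 and 2.61 to 3.27 in the rest. The score of the synovial sarcoma list ran from -0.36 in tumour 5 to 0.19 in tumour 6. All 18 BAF and Polycomb subunits passed. The fusion partner Ss18 stood at 11.43 ± 0.25, the BAF ATPase Smarca4 at 10.72 ± 0.33 and the core subunit Smarcb1 at 9.54 ± 0.24. Every member of that list was higher in tumour 5 than the median of the others, by a median of 0.41 (SD over members 0.36). Limb position genes passed for 9 of 11, and for 5 at the 99th percentile of background. Pitx1, the hindlimb selector, had 7.17 ± 1.09, Tbx4 had 7.19 ± 0.55 and Hoxc10 had 10.43 ± 0.68. The forelimb gene Tbx5 did not pass as a mean (4.13 ± 1.68), but exceeded the threshold in tumours 3 and 5, at 5.37 and 6.63. Epithelial genes, the glandular element of biphasic synovial sarcoma, passed for 8 of 16, for 3 at that stricter percentile and for 5 when each tumour had to exceed its threshold. The keratins Krt8 and Krt18 had means of 6.59 ± 1.22 and 7.06 ± 1.97 and the adhesion molecule Epcam had 9.66 ± 1.25. Krt18 ranged from 4.24 in tumour 1 to 9.39 in tumour 2. The epithelial score was lowest in tumour 5 (-1.11).

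Transcripts of mature skeletal muscle were far lower in tumour 5 than in the other tumours. All 20 members lay above background. Creatine kinase Ckm had a mean of 12.23 ± 1.67, skeletal actin Acta1 had 12.99 ± 1.32 and the fast myosin Myh4 had 11.83 ± 1.82. In tumour 5 all 20 members were below the median of the other tumours, with a median shift of -3.81 (14-fold; SD over members 0.54). In tumour 3 all 20 were above it, by a median of 1.37 (SD 0.72). The members moved together, with a mean pairwise correlation of 0.953, and their median SD of 1.81 lay at the 100th percentile of 10000 random lists. The median SDs of macrophage and of matrix and fibroblast genes lay there too. Without tumour 5 that SD was 0.66. Myogenic genes, a list of regulators and of other genes of forming muscle, passed for 8 of 13. When each tumour had to exceed its threshold, 5 passed. The regulators Pax3, Myf6 and Msc passed, and the rest that passed were Des, Myh3, Myh8, Chrna1 and Cdh15, which are not regulators. Myod1 and Myog, which drive myoblast differentiation, had means of 5.18 ± 1.26 and 5.07 ± 1.57 and did not pass as means. Both exceeded the threshold in tumours 2, 3, 4 and 6, at 5.44 to 6.44 and 5.31 to 6.61. They were below it in tumour 1 (4.68 and 3.67) and tumour 5 (2.89 and 2.69). The satellite-cell gene Pax7 did not pass as a mean either, at 6.32 ± 2.65. Pax7 reached 9.87 in tumour 3 and 9.07 in tumour 5.

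Matrix, macrophage and endothelial scores were also lowest in tumour 5. All 14 matrix and fibroblast genes passed, among them the collagens Col1a1 (13.45 ± 0.24) and Col3a1 (13.91 ± 0.28) and fibronectin, Fn1 (12.98 ± 0.80), with all 14 below the median of the others in tumour 5 and a median shift of -1.56 (SD over members 1.09). Several of these genes, Col1a1 and Col3a1 included, lay near the top of the scale, where differences between tumours are compressed. All 14 macrophage genes passed. Adgre1, the F4/80 antigen, had 10.72 ± 0.83, Csf1r, the receptor that maintains macrophages, had 12.04 ± 0.97 and Cd68 had 9.89 ± 1.34. Their shift in tumour 5 was a median of -1.90 (SD 0.52) and in tumour 3 it was -1.20 (SD 0.46). Endothelial genes passed for 11 of 11, with Pecam1 at 7.86 ± 0.73, Cdh5 at 10.42 ± 0.67 and Kdr at 10.60 ± 0.46, and all 11 were lower in tumour 5 than the median of the others, with a median shift of -1.25 (SD over members 0.26). Mural cell genes passed for 8 of 8, with Acta2 at 12.43 ± 0.45, Rgs5 at 11.82 ± 0.51 and Myh11 at 7.98 ± 0.61.

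Cartilage and bone genes passed for 9 of 10, including the chondrocyte regulator Sox9 (7.26 ± 0.80), aggrecan, Acan (7.72 ± 1.79), and Col2a1 (11.13 ± 0.51). Tendon and joint genes passed for 6 of 8. Tenomodulin, Tnmd, had 8.54 ± 1.26 and lubricin, Prg4, had 8.60 ± 2.17, while the tendon regulator Scx stayed below background at 3.93 ± 0.49. In tumour 5 the median shifts of these 2 lists were -2.54 (SD over members 1.80) and -3.38 (SD 1.5). Fat cell genes passed for 5 of 8 (3 at the 99th percentile of background), with Adipoq at 8.83 ± 0.56 and Fabp4 at 11.24 ± 0.68, and Lep below background.

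Lymphoid genes passed in part. T and NK cell genes passed for 4 of 11 and for 1 at the 99th percentile of background, and Cd3e (4.14 ± 1.05) and Gzmb (2.18 ± 0.87) were below it, with Cd8a at 5.71 ± 0.52. Of the B and plasma cell genes 4 of 8 passed (2 at that percentile), namely Jchain (8.99 ± 1.61), Ighm (9.27 ± 0.45), Cd22 (6.20 ± 0.63) and Mzb1 (5.94 ± 0.53), while Cd79a, Ms4a1 and Cd79b did not. Neutrophil genes passed for 5 of 8 (3 when each tumour had to exceed its threshold), with S100a8 at 11.16 ± 1.36, S100a9 at 10.19 ± 1.38 and the granule enzyme Mpo at 7.38 ± 1.27. Their score was 2.09 in tumour 1, 1.91 in tumour 2 and -2.75 in tumour 5. Erythroid genes passed for 3 of 5, Schwann cell genes for 3 of 5 and keratinocyte genes for 3 of 6. Alas2 (8.11 ± 2.46) and Slc4a1 (7.33 ± 2.80), S100b (8.82 ± 2.29) and Mbp (6.41 ± 0.41), and Krt10 (8.41 ± 0.18) and Lor (6.18 ± 0.23) were among them, and Hba-a1, Sox10 and Krt1 were not. Of the sex-linked genes only Xist passed, at 13.17 ± 0.06 in the 6 tumours, and Eif2s3y, Kdm5d and Uty, on the Y chromosome, did not pass.

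Cell-division genes were present and varied together. All 20 passed. Mki67 had a mean of 10.21 ± 0.59, Top2a had 10.14 ± 0.61 and Ccnb2 had 8.87 ± 0.65. The score was highest in tumour 5 (0.84) and lowest in tumour 6 (-0.68), and all 20 members lay above the median of the others in tumour 5, by a median of 0.87 (1.82-fold; SD over members 0.23). Interferon-response genes passed for 7 of 7, with Ifit1, Irf7 and Ifit3 at 9.07 ± 0.82, 9.19 ± 0.80 and 8.12 ± 0.96. Hypoxia and glycolysis genes passed for 9 of 10, with Vegfa at 9.58 ± 0.40, the glucose transporter Slc2a1 at 9.85 ± 0.93 and Car9 below background. Both lists were lowest in tumour 5, with scores of -1.16 and -1.23. Immediate early genes passed for 10 of 10, including Fos (10.59 ± 0.14), Egr1 (11.64 ± 0.08) and Hspa1a (7.72 ± 0.45). All 7 housekeeping genes, 4 of them near the top of the scale, passed and stayed within a score of -0.05 to 0.06, with Actb at 13.67 ± 0.04, Gapdh at 13.30 ± 0.10 and Hprt at 10.69 ± 0.09.

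**Figure D2:**
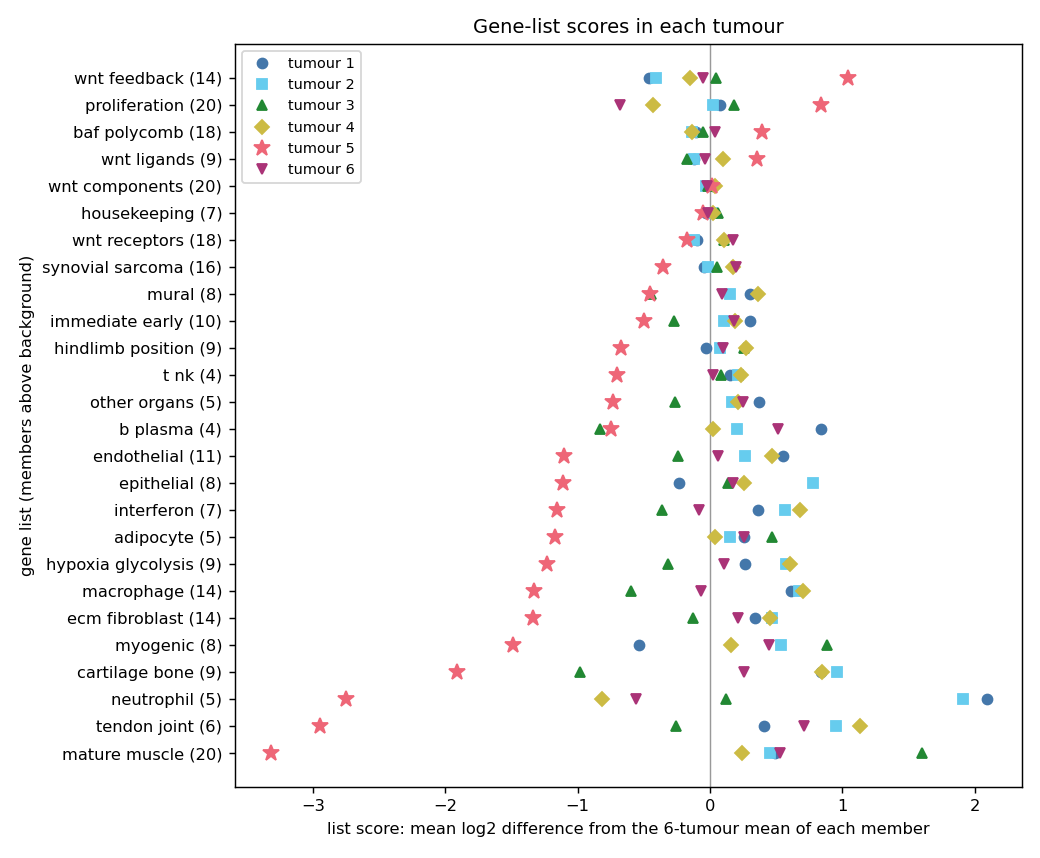
Scores of the 26 gene lists with at least 4 members above background, 1 row per list with its number of members, each symbol being 1 tumour and the x axis the mean log2 deviation of the members from their 6-tumour means. Tumour 5 (star) lies highest for Wnt feedback (1.04), proliferation (0.84) and BAF and Polycomb (0.40), and lowest for mature muscle (-3.32) and tendon and joint (-2.95).

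No single gene was called more variable than genes of like level. The test of each gene's variance against limma's fitted prior passed 0 of 12581 genes, with a smallest adjusted p of 0.872 and 698 genes at an unadjusted p under 0.05. The fitted prior had only 2.08 degrees of freedom, because variances differed widely between genes. Simulated data took the spread of variances from all 18194 genes, dim ones included. There the test called 0 of 50 genes at a 20-fold larger SD and 3 of 50 at a 40-fold larger SD. The first principal component held 60.4% of the variance over genes above background and the second 22.8%. On the first, tumour 5 scored 89.4, tumour 3 scored 15.1 and the other 4 lay between -31.5 and -14.9. On the second, tumour 3 scored 58.4 and the others lay between -20.8 and -7.23.

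A set of 8 correlations between list scores, fixed before the data were examined, asked whether Wnt target levels or muscle content went with other programmes. Wnt feedback scores were lower in tumours with more matrix and fibroblast signal, with a Pearson r of -0.967 (exact permutation p = 0.0125, two-sided, n = 6) and a Spearman rho of -0.829 (exact permutation p = 0.0583). They were also lower in tumours with more macrophage signal, with r = -0.915 (exact permutation p = 0.00833, n = 6) and rho = -0.771 (exact permutation p = 0.103). Both had a Benjamini-Hochberg adjusted p of 0.05 over the 8 pairs, which is at the threshold and not under it. The permutations can give no p below 1 in 720. These 2 relations are not independent, since matrix and macrophage scores were both highest in tumours 1, 2 and 4 and lowest in tumours 3 and 5. Endothelial and interferon scores were too, but were not among the pairs tested, so the pattern was not particular to matrix or macrophage genes. Without the 2 tumours farthest from the median Wnt score (1 and 5), r was -0.82 for matrix and -0.831 for macrophages over 4 tumours, and without tumour 5 alone r was -0.727 and -0.818, with an adjusted p of 0.343 for each by the exact permutation test. The other 6 pairs each had an adjusted p of 0.192. Wnt feedback against mature muscle had r = -0.833 (exact permutation p = 0.149) and rho = -0.0857 (exact permutation p = 0.919), and r was 0.629 without the 2 farthest tumours. Against proliferation r was 0.653 (exact permutation p = 0.179) with rho = 0.429 (exact permutation p = 0.419), and r was -0.123 without the 2 farthest. Against synovial sarcoma genes r was -0.694 (exact permutation p = 0.153) with rho = -0.0286 (exact permutation p = 1), and r was 0.501 without them.

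Mature muscle against proliferation, macrophage and matrix scores gave r of -0.653, 0.597 and 0.825 (exact permutation p = 0.189, 0.192 and 0.165). The rho values were -0.2, -0.143 and -0.0857 (exact permutation p = 0.714, 0.803 and 0.919). Without the 2 tumours farthest from the median muscle score (3 and 5), r was 0.122, -0.589 and -0.68. The signs of these 3 and of the 3 Wnt relations with muscle, proliferation and synovial sarcoma genes therefore rested on the tumours left out, tumour 5 being among them in every case. No batch could be examined, because the labels used here give none.

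**Figure D3:**
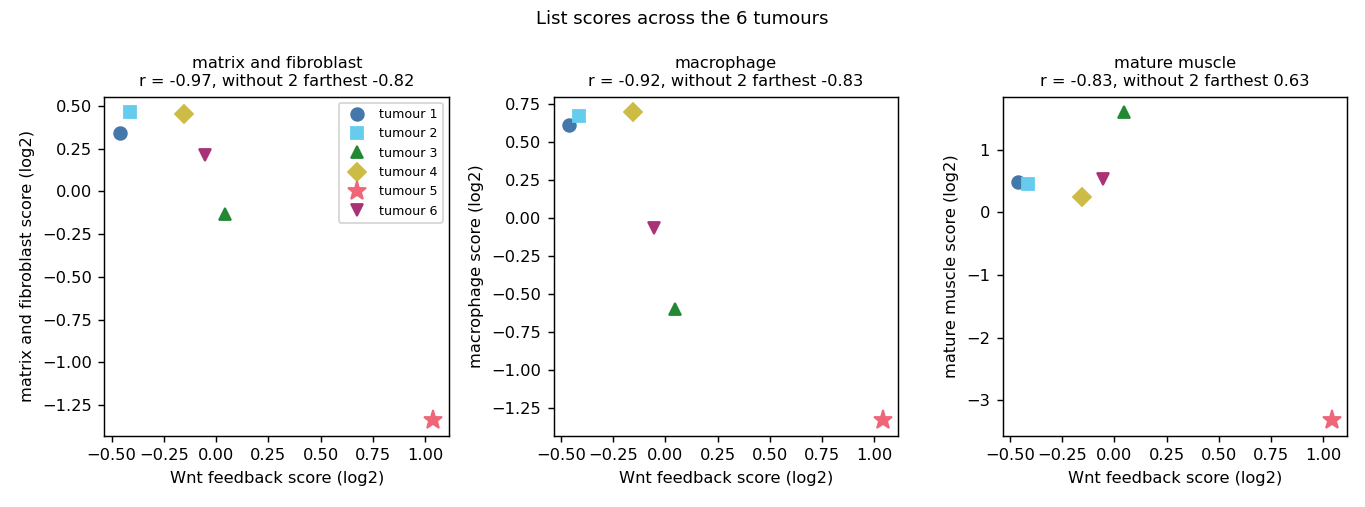
Wnt feedback score (x axis, log2) against matrix and fibroblast, macrophage and mature muscle scores (y axes, log2), each symbol being 1 of the 6 tumours, with Pearson's r over all tumours and without the 2 farthest from the median x score. The negative relation keeps its sign in the first 2 panels (-0.82 and -0.83) and turns positive (0.63) for mature muscle.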

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

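All tests of explanations in this part were chosen after the results were seen. The results listed here had a tumour whose gap to its nearest neighbour took up more of the 6-tumour range than Dixon's 95% critical value allows, which chance gives for about 1 in 20 groups. Over all 12581 genes above background 1350 (10.7%) did so, 768 of them through tumour 5 and 371 through tumour 3. Of 26 list scores 8 did so, each through tumour 5. The gap was 0.663 of the range for Wnt feedback and 0.672 for BAF and Polycomb, where tumour 5 was highest. Tumour 5 was lowest for hindlimb position (0.674), matrix and fibroblast (0.67), tendon and joint (0.659), mature muscle (0.724), adipocyte (0.735) and T and NK cell genes (0.775). Of 79 named genes above background 16 did so. Tumour 5 was highest for Lef1 (0.632), Smarca4 (0.666) and Smarcb1 (0.744). It was lowest for Col3a1 (0.905), Sox9 (0.65), Tnmd (0.643), Ckm (0.687), Acta1 (0.823), Myh4 (0.63), Cd8a (0.791), Kdr (0.645), Rgs5 (0.76) and S100b (0.774). Tumour 3 was highest for Fzd2 (0.627) and lowest for Wif1 (0.711), and tumour 4 was highest for Lor (0.746), a cornified envelope gene of skin. The low hindlimb score came from other members than Pitx1 and Tbx4, which were above the median of the others in tumour 5 by 1.78 and 0.31.

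Tumour 5 stood apart across many programmes. Scaling of its array by 1 factor is argued against by lists that moved in opposite directions. The median shift of proliferation genes was 0.867 and that of endothelial genes -1.25, a difference of 2.12 against a summed SD over members of 0.487, with 0 members of either list near the top of the scale. Housekeeping genes cannot serve here, since 4 of 7 lie near that top. Whether degraded RNA contributed cannot be told apart. The 3′ probe sets of Actb and Gapdh lie near the top of the scale too, and the 5′ probe set of Tfrc lies below background, which leaves Pcx, whose 3′ to 5′ signal ratio in tumour 5 was 5.11, inside the 2.68 to 6.21 of the other arrays. The 18S ribosomal RNA signal was highest in tumour 5 (6641) and next in tumour 3 (4930), and a difference in RNA preparation was not tested. A larger share of tumour cells that diluted every other cell type alike is argued against too, since the shift of muscle was lower than that of endothelial genes by a difference of -2.56, beyond the 0.793 that their SDs over members add up to. Whether Wnt targets rose beyond what a larger share of tumour cells might give cannot be told apart. Their median shift exceeded that of proliferation genes by 0.310, within a summed SD of 1.36. Of the Wnt members 3 lay near the top of the scale, where shifts are compressed (Apcdd1 -0.04, Wif1 -0.07 and Tnfrsf19 0.27). The 0.310 may therefore understate the rise. Synovial sarcoma genes above background go against a larger share, with 11 of 16 lower in tumour 5. Their median shift of -0.194 lay within the SD over members of 0.827 and so decides nothing. That count also leaves out Sox2 and Zic2, which did not pass as means and were higher in tumour 5 by 2.82 and 4.94. The design names no second group, and no explanation beyond these was tested.

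Muscle transcripts differed between tumours with a median SD of 1.81, which was 0.661 without tumour 5. Whether differing amounts of adult muscle in the specimens account for the levels cannot be told apart from other causes. The SD of the shifts of the 20 fibre genes was 0.141 of the median shift in tumour 5, where single genes were 5.67-fold to 33.3-fold lower, but 0.527 of it in tumour 3, where 15 of the 20 lay near the top of the scale. Fast and slow fibre genes go against a single muscle of fixed fibre mix. They do not decide it, because both lists were written after the values were seen. The slow minus fast score was -2.15, 1.74, -0.992, 0.254 and 1.86 in tumours 1, 2, 3, 4 and 6, a range of 4.01 against a summed SD of 1.36. Which muscles, if any, the specimens adjoined stays open, and no other explanation was tested.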

How the results depend on the processing

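Settings that left out a tumour from a correlation, left out members near the top of the scale or dropped 2 olfactory receptors were chosen after seeing the data, and the cause of each change below was not tested. Genes above background (10856 to 12817) and Wnt targets above background (13 to 14) stayed within 1.5 times their main counts in every setting, and 0 variable genes were called in each of the 14 settings run, with 608 to 1039 at an unadjusted p under 0.05. Wnt coherence was 0.431 without members near the top of the scale and 0.0751 to 0.362 with 1 tumour left out, lowest without tumour 5. The median SD with 1 tumour left out was 0.495 to 0.724 for Wnt feedback and 0.661 to 2.01 for mature muscle, both lowest without tumour 5. The first component's share was 42.4% with genes scaled to unit SD and 60.4% to 77.9% with 1 tumour left out, highest without tumour 3. The 2 Wnt relations at the threshold passed it, with adjusted p = 0.0333 by exact permutation, under quantile normalization (matrix -0.978, macrophage -0.922), with all measured members (-0.975 and -0.939) and without members near the top of the scale (-0.965 and -0.921). Over all their settings the adjusted p ran from 0.0333 to 0.6 and both stayed negative, at -0.984 to -0.727 and -0.963 to -0.818 with 1 tumour left out. Signs turned without the 2 farthest tumours for Wnt feedback with proliferation (-0.124), synovial sarcoma genes (0.502) and muscle (0.629), and for muscle with proliferation (0.122), macrophage (-0.589) and matrix scores (-0.68). With all measured members the synovial sarcoma relation was 0.309, and Spearman's rho was -0.143 for muscle with macrophage and -0.0857 with matrix scores. With 1 tumour left out, these 6 ran from -0.32 to 0.804, -0.817 to 0.693, -0.961 to 0.591, -0.835 to 0.536, -0.884 to 0.915 and -0.95 to 0.983, turning only without tumour 5. Of the values of single lists, 228 moved by less than their spread or 1.5 times, 51 moved further and 0 turned. Genes within about 1 log2 unit of the threshold are the least certain, since 33 of 50 simulated genes at 0.5 above it were called. No paired analysis was possible because the labels name 1 group only.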

Other observations

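The tests of explanations and the gene lists in this part were chosen after the values were seen. Osteoclast genes formed a block in 3 tumours. Acp5, the tartrate-resistant phosphatase of osteoclasts, stood at 12.79, 13.04 and 12.80 in tumours 1, 2 and 4 and at 10.44, 7.20 and 8.71 in tumours 3, 5 and 6. Ctsk, the collagen-degrading protease of bone resorption, had 12.91, 13.13 and 12.98 in the first 3 of these and 11.43, 9.15 and 10.86 in the others, and Mmp9, Atp6v0d2 and Dcstamp were also higher in tumours 1, 2 and 4 than in the rest. Car2 was an exception, with 8.31 in tumour 3 and 8.14 in tumour 1. The score over all 9 measured members, of which 7 lay above background, was 1.35, 2.06, -0.71, 1.63, -2.85 and -1.49 in tumours 1 to 6, with a mean pairwise correlation of 0.954. Macrophages share part of this list, and the macrophage score had much the same order. It was highest in tumours 1, 2 and 4 (0.615, 0.674 and 0.699) and low in tumours 3 and 5 (-0.594 and -1.33). It differed in tumour 6, at -0.07. The matrix and fibroblast score was highest in tumours 1, 2 and 4 too, so this pattern was not particular to osteoclast genes. Precursor neutrophil genes were highest in tumours 1 and 2, with scores over all 6 measured members, of which 4 passed, of 2.42 and 1.96 against -2.69 in tumour 5. Camp, an antimicrobial granule peptide, had 10.61 and 9.88 in those tumours and 3.41 in tumour 5. The score of 4 immunoglobulin and plasma cell genes was highest in tumour 1 (1.13) and lowest in tumour 3 (-1.37), as were Igha (11.99 and 7.82) and Jchain, whereas Ighm was highest in tumour 6 (10.11) and both Ighm and Mzb1 were lowest in tumour 5. Myoblast genes passed the background test as means for 2 of 6, namely Myh3 and Cdh15, while Myod1 and Myog exceeded the threshold in 4 tumours each.

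The genes that follow were picked from those with a large SD between tumours. Chil1, a chitinase-like secreted protein, had 12.88, 13.59, 12.97, 13.60 and 13.22 in tumours 1, 2, 3, 4 and 6 and 5.22 in tumour 5. Mmp13, a collagenase of cartilage and bone remodelling, ran from 5.49 in tumour 5 to 12.88 in tumour 2, and Dmp1, a bone matrix protein, from 4.85 in tumour 3 to 11.73 in tumour 1. Slow fibre genes spread widely too. Myh7, the slow myosin, had 11.36 and 11.31 in tumours 2 and 6 but 6.00 in tumour 1. Hdc, the histamine-forming enzyme, had 12.66 in tumour 5 and 4.81 to 8.57 in the others. None of these genes passed the variability test, whose smallest adjusted p with limma's prior was 0.872.

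A set of transcription factor genes picked from these data was higher in tumours 3 and 5 than in the other tumours. Pax3 had 11.32 and 11.95 in tumours 3 and 5 against 4.57 to 8.12 elsewhere, Zic5 had 10.70 and 10.83 against 3.87 to 6.68, and Lhx2 had 9.30 and 11.03 against 4.36 to 6.55. Noise near the background threshold was examined on another probe set of these genes, where present, which was not used to pick them. Tumours 3 and 5 were the highest pair on that probe set for 3 of 4 genes (Pax3, Pax7 and Zic5, but not Foxd2). For these 3 the pattern did not rest on 1 probe set. Chance would give 0.267 genes (binomial p = 0.00113) if genes were independent and every pair of tumours as likely to be highest. That was not checked, and tumours 3 and 5 stood apart in many genes, so this p does not decide against noise. The other genes of the set, Lhx2, Zic2, Foxd1 and Sox2, have no other probe set. For Lhx2, Zic2 and Foxd1 the lowest value over the threshold in tumours 3 and 5 was 4.28. No olfactory receptor probe set lay more than 2.48 above the threshold on any array. These values cannot decide against noise, because the genes were picked for being high in these tumours. For Sox2, whose lowest was 1.33, in tumour 5, noise cannot be told apart there, because background reached as high. In tumour 3 Sox2 had 8.82 against a threshold of 5.02, beyond that reach, but it too was picked for being high. Less tissue of every other cell type is argued against in tumour 3 by mature muscle. Its median shift there was 1.37 (SD over members 0.723) while macrophage genes shifted by -1.20. In tumour 5 mature muscle, macrophage and endothelial genes were all lower (-3.81, -1.90 and -1.25), so for that tumour this explanation stays open. The list came from these data, and no other explanation was tested.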
